A study of Mus musculus with 4 samples.

How the data were processed

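Macrophages were grown from bone marrow of C57BL/6 mice carrying transplanted wild-type or Bcl6 knockout marrow, and each of the 4 samples was hybridised to 1 Affymetrix array (2 wild-type, 2 knockout). Per the labels' protocols, marrow was cultured for 5 days in medium with 20% fetal bovine serum and 30% L929-conditioned medium, moved overnight to serum-free medium and lysed in Trizol, and biotin-labelled cRNA was made from 5 µg of total RNA. The labels call the arrays biological replicates but do not say whether each came from its own mouse or culture, so p-values measure the spread between these arrays, which may be partly technical.

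The deposited values are signal intensity on a linear scale, 1 value per probe set and array. The submitters' processing notes name MAS5, and its version and the array build are not given in the sources used here. On every array the mean signal after trimming 2% from each end was 200, so the authors had scaled each array to a common level, and no further normalization was applied in the main analysis. The table holds 45037 probe sets besides 64 controls. Gene names came from the platform annotation: 34945 probe sets have 1 gene symbol, 932 have several and were not named, and 9160 are not listed there. Entrez gene numbers of 34754 probe sets matched a mouse gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for names and for the order of neighbouring genes; no coordinates are given because the files name no genome build.

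Each of 18193 genes was represented by its probe set with the highest mean signal over the 4 arrays. Probe sets with a mean signal above the median of all non-control probe sets (30.925) were kept, which left 10814 genes. Signals were tested as log2(signal + 16) with limma (version 3.58.1, in R 4.3.3; lmFit, and eBayes with an intensity trend), with genotype as the only term and Benjamini-Hochberg adjustment over all tested genes; a gene changed if its adjusted p was under 0.05. Fold changes are knockout minus wild-type on this log2 scale, which understates the change of dim genes. The 2 Bcl6 probe sets were tested in a fit of all 22515 probe sets above the filter. With 2 arrays against 2, an exact permutation test cannot give a two-sided p below 0.333, so no gene was tested that way. Errors printed with ± are SDs of 2 arrays.

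Background was taken from 27 probe sets for bacterial RNA that read low on all arrays. Their highest signal was 18.5 and 30.6 on the wild-type arrays and 21.6 and 20.3 on the knockout arrays. A gene at or below this level on both arrays of a genotype has only a bound there, and its fold is given as at least the bright genotype's mean log2 signal over the mean log2 of these highest control signals. Genes at that level on only 1 array of a genotype keep their fitted value, which is then less certain; among genes named in the text these are Car2, Il1a and Siglecf in wild-type and Cfb, Cxcl14, Fpr2, Lox and Neurl3 in the knockout. F3 is also at that level on only 1 wild-type array, but its other wild-type signal is so close to the controls that no fold is given. The depth of the measurement is set by the number of arrays.

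Before the data were examined, 26 gene lists were fixed for macrophage pathways, for macrophage identity and for other cells that a marrow culture could hold, along with the tests, the alternatives and the rule for naming genes. The lists hold 628 distinct symbols, of which 570 are on the array. The 22 lists with at least 5 tested genes were compared with all other genes by limma's camera (two-sided, inter-gene correlation 0.01, adjusted over the 22 lists). Beside each list stands the number of members past the threshold over all genes and adjusted over the list alone. A list of sex-linked genes served to check the samples, and 3 lists with fewer tested genes are given as values. Some genes stand on more than 1 list. Named genes are the 12 with the largest increase and the 12 with the largest decrease among changed genes whose knockout arrays both lie on 1 side of both wild-type arrays, Bcl6, the sex-linked genes, and up to 4 members of each list with the smallest unadjusted p; others are said to have been named after their values were seen.

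The alternatives were pseudocounts of 1 and 64, no filter and a filter at the 75th percentile, quantile normalization, centring each array on its median (median scaling), the mean of all probe sets of a gene, all probe sets, leaving out probe sets that can bind RNA of several genes, eBayes without a trend, the replicate number as a block, an adjusted p under 0.1, a correlation estimated for each list, and leaving out each array in turn. With 1 array left out, the lone array of its genotype is taken to vary like the other genotype's arrays. The procedure was tested on 20 simulated data sets of 2 arrays against 2 with 200 changed genes each (10894 genes tested in the first). It called 62.3% of 2-fold and 86.4% of 4-fold changes, 5.12% of its calls were false and 0 had the wrong sign. In 20 data sets with no changed gene it called 0.1 genes on average and no list. The simulated genes varied independently of each other and equally in both genotypes. These runs therefore do not test list calls, or the share of false calls, among genes that vary together.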

Results

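Gene expression was measured in primary macrophages grown from the bone marrow of male C57BL/6 mice that had been reconstituted with wild-type or Bcl6 knockout marrow. Bcl6 encodes a zinc finger repressor of transcription best known from germinal centre B cells. The mice were 16 weeks old, 6 weeks after transplant. Marrow was differentiated for 5 days with L929-conditioned medium, a source of the macrophage growth factor Csf1, and the cells then spent a night without serum before RNA was taken. There were 2 arrays per genotype, 4 in all, each with 45037 probe sets besides controls, and the number of arrays limits the precision of every value. The median signal was 31.6 and 35.6 on the wild-type arrays and 29.0 and 33.0 on the knockout arrays. Across the 10814 tested genes, with 1 probe set each, log2(signal + 16) correlated at r = 0.990 between the wild-type arrays. The correlation was 0.983 between the knockout arrays and 0.960 to 0.967 between genotypes. These are correlations across genes, which are not independent replicates. The 3' to 5' signal ratio of actin, a sign of RNA quality, was 1.15 and 1.19 on the wild-type arrays against 1.22 and 1.33 on the knockout arrays. For Gapdh it was 0.765 and 0.742 against 0.813 and 0.785. These ratios were thus higher on both knockout arrays than on both wild-type arrays. The Y-linked gene Eif2s3y gave signals from 707 to 938 over the 4 arrays, Kdm5d from 174 to 240 and Uty from 176 to 319, each at its brightest probe set. The highest signal of any Xist probe set was 71.2.

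To check the genotype labels, the 2 Bcl6 probe sets were examined first, and they differed in sign. Probe set 1450381_a_at was 2.52-fold lower in knockout macrophages, at 58.4 ± 3.04 against 171 ± 5.23 in wild-type (mean ± SD, n = 2 each; log2 fold change -1.33, SE 0.17, limma adjusted p = 0.00178). Probe set 1421818_at, the brighter of the pair, gave 873 ± 13.8 in the knockout and 667 ± 97.4 in wild-type (log2 fold change 0.39, SE 0.12), and did not pass the threshold (adjusted p = 0.0841). It passed when each array was centred on its median (log2 fold change 0.48, adjusted p = 0.0435), and over all alternatives its adjusted p ranged from 0.0225 to 0.615. The labels do not say which part of Bcl6 was deleted, so a probe set outside that part checks nothing. The fall at 1450381_a_at was far larger than the gap between replicates.

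**Figure D1:**
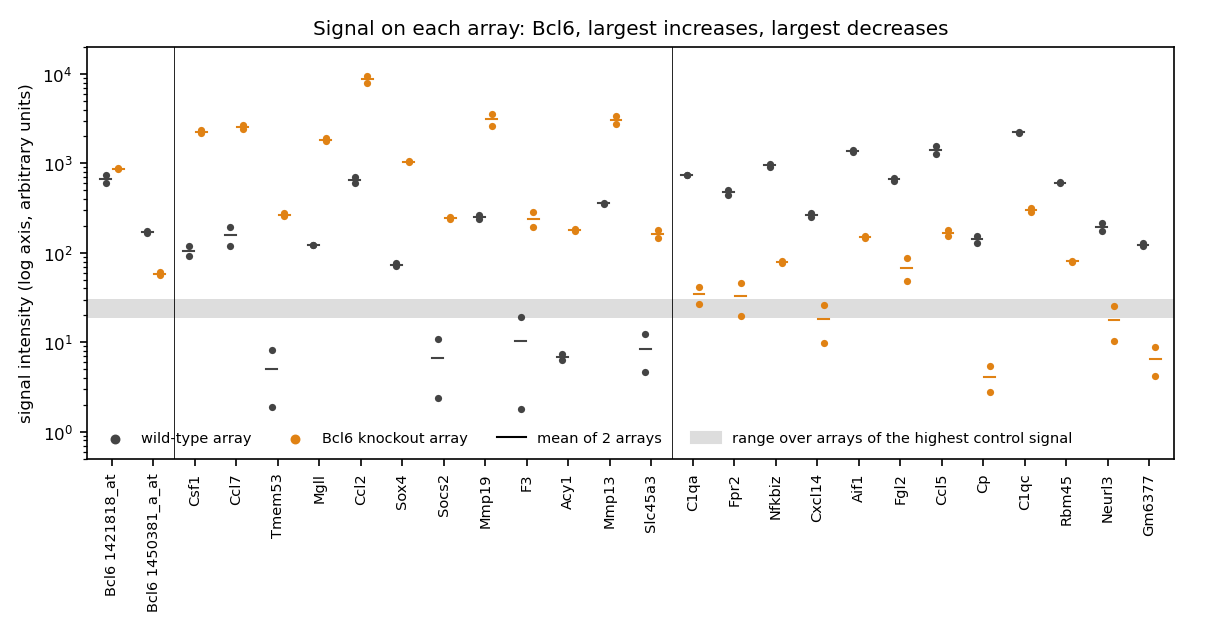
Signal intensity on each of the 4 arrays (log axis, arbitrary units) for the 2 Bcl6 probe sets, the 12 genes with the largest increase and the 12 with the largest decrease in Bcl6 knockout macrophages; dots are single arrays, bars the mean of 2 arrays, and the grey band spans the highest bacterial control signal of each array (18.5 to 30.6). In each of the 24 genes both knockout arrays lie on 1 side of both wild-type arrays.

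The comparison of knockout with wild-type macrophages asked which genes depend on Bcl6 in this cell type. Knockout cells had far more RNA for the growth factor Csf1 and the monocyte attractants Ccl2 and Ccl7, and for the proteases Mmp13, Mmp19 and Mmp8. They had far less for the 3 chains of the complement protein C1q, for the chemokine Ccl5 and for the NF-kB cofactor Nfkbiz. Of the gene lists tested at a preset inter-gene correlation, those of chemokines, matrix proteases, cholesterol synthesis, fatty acid oxidation, erythroid and platelet markers and ER stress lay above all other genes, and those of interferon-stimulated and Toll-like receptor genes below them. With an estimated correlation none of these lists passed (adjusted p between 0.429 and 0.569). That test has 2 residual degrees of freedom and could hardly pass any list, so nothing is concluded from its outcome. In all, 1691 of 10814 tested genes changed at an adjusted p under 0.05, with 791 higher and 900 lower in the knockout. Of these, 166 were at least 2-fold higher and 178 at least 2-fold lower. These 2-fold counts depend on the pseudocount: they were 106 and 96 with a pseudocount of 64, and 183 and 197 with 1. The unadjusted p was under 0.05 for 3174 genes. Both knockout arrays lay on 1 side of both wild-type arrays for 58.8% of tested genes, where chance gives 33.3%. When each array was centred on its median, which moved the median log2 fold change of all genes from -0.04 to 0.05, 980 genes were higher and 570 lower. The count fell to 585 without wild-type array 1 and to 579 without wild-type array 2, and rose to 2799 without knockout array 1. The 3' to 5' ratio of actin moved with genotype too, from 1.15 and 1.19 to 1.22 and 1.33. The counts of genes changed at least 2-fold moved less, from 155 to 197 higher and from 140 to 264 lower over the 4 fits with 1 array left out.

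**Figure D2:**
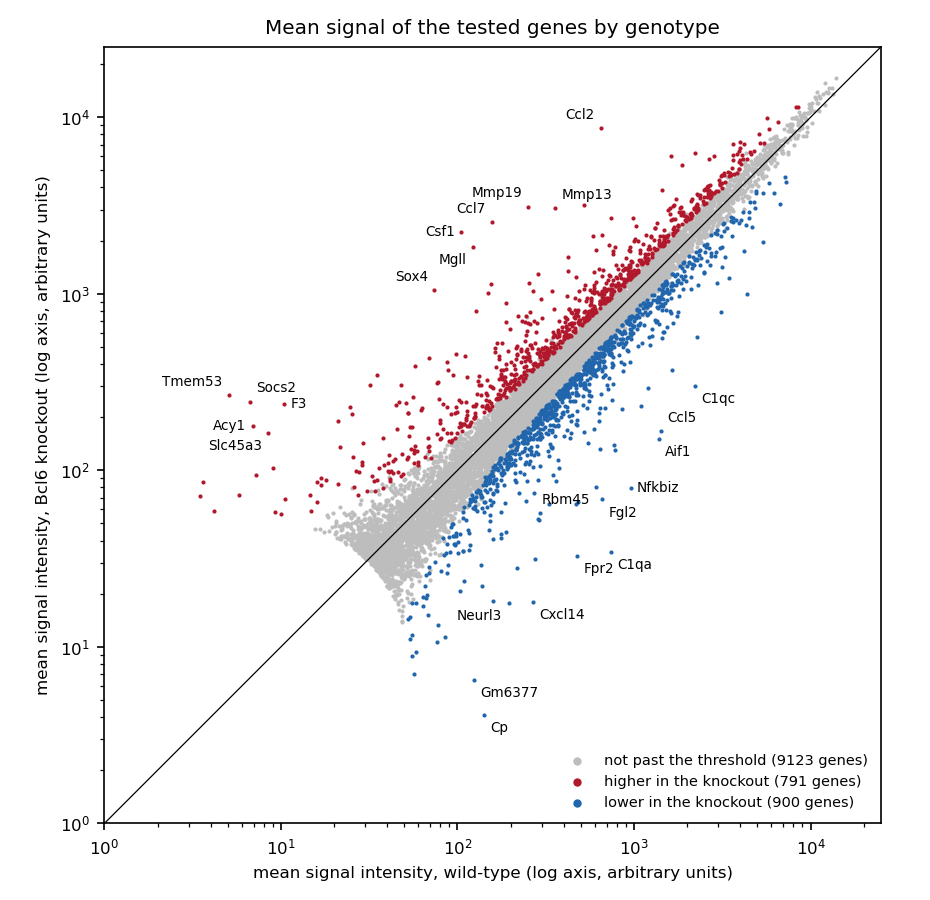
Mean signal intensity of the 10814 tested genes in wild-type (x axis) and Bcl6 knockout macrophages (y axis), both on log axes in arbitrary units, 2 arrays per genotype. Red points are the 791 genes higher in the knockout, blue points the 900 lower and grey points those not past the adjusted p threshold; the line marks equal signal, and the 24 genes with the largest changes are named.

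On the log2(signal + 16) scale, Csf1 had the largest increase of the tested genes. Its signal was 105 ± 18.1 in wild-type and 2248 ± 124 in knockout macrophages (SD, n = 2 each), a log2 fold change of 4.23 (SE 0.13, adjusted p = 9.72e-08). Ccl7 rose from 156 ± 50.6 to 2538 ± 181 (log2 fold change 3.92, SE 0.17, adjusted p = 5.75e-07), and Ccl2 from 648 ± 68.9 to 8719 ± 1041 (3.72, SE 0.12, adjusted p = 1.25e-07). The transcription factor gene Sox4 went from 73.7 ± 3.61 to 1047 ± 33.6, a log2 fold change of 3.57 (SE 0.12). Mgll, which encodes a lipase that cleaves monoacylglycerols, rose with a log2 fold change of 3.75 (SE 0.11). Mmp19 and Mmp13 rose with log2 fold changes of 3.53 (SE 0.14) and 3.03 (SE 0.12). F3, the tissue factor that starts blood clotting, rose to 282.7 and 193.5 on the knockout arrays. Its wild-type signals, 19.0 and 1.8, lay near or below the highest bacterial controls of their arrays (18.5 and 30.6), so no fold is given. For 4 more genes of this group both wild-type arrays were at the level of the bacterial controls, so only a lower bound can be given, and their rank beside Csf1 is open. Tmem53 was at least 11.2-fold higher in the knockout, Socs2, an inhibitor of cytokine signalling, at least 10.3-fold, the aminoacylase gene Acy1 at least 7.52-fold and the transporter gene Slc45a3 at least 6.82-fold. Of 2 other Socs2 probe sets above the filter, 1 moved the other way without passing the threshold. The adjusted p of all 12 genes was 0.000144 or lower.

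On the same scale the largest decrease was that of C1qa, which fell from 740 ± 1.84 in wild-type to 34.4 ± 10.7 in the knockout (SD, n = 2 each; log2 fold change -3.93, SE 0.17, adjusted p = 4.57e-07). C1qc fell from 2215 ± 53.0 to 302 ± 18.2 (log2 fold change -2.81, SE 0.10). Nfkbiz, whose protein joins NF-kB to switch on secondary response genes, fell from 959 ± 52.9 to 79.5 ± 2.55 (log2 fold change -3.35, SE 0.12, adjusted p = 1.75e-07). The formyl peptide receptor gene Fpr2 had a log2 fold change of -3.38 (SE 0.24), the macrophage calcium-binding protein gene Aif1 of -3.07 (SE 0.11) and Fgl2, which encodes a fibrinogen-like protein, of -3.04 (SE 0.20). The chemokine genes Cxcl14 and Ccl5 fell with log2 fold changes of -3.09 (SE 0.25) and -2.97 (SE 0.13). Rbm45 and Neurl3 had -2.70 (SE 0.13) and -2.67 (SE 0.27). Both knockout arrays were at the level of the bacterial controls for Cp, which encodes the copper carrier ceruloplasmin, and for Gm6377. Cp was at least 6.74-fold lower and Gm6377 at least 5.91-fold lower, and their rank beside C1qa is open. For Fpr2, Cxcl14 and Neurl3, 1 of the 2 knockout arrays was at that level, so the size of their fall is less certain. The only probe set of Gm6377 above the filter is of a kind that can bind RNA of several genes. The adjusted p of these 12 genes was 0.000244 or lower.

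Chemokine genes moved in both directions, more of them upward. Of 18 tested CC and CXC chemokine genes, 12 rose, 4 fell and 2 did not pass (12 rose and 5 fell adjusted over the list alone). The list lay above all other genes (camera adjusted p = 0.00299; adjusted p = 0.429 with an estimated correlation). None of the lists called in this comparison passed with an estimated correlation. Beside Ccl2 and Ccl7, the increases took in Ccl8, Ccl3, Ccl6 and Ccl24, named after their values were seen, as was Cxcl10, which fell. The decreases were those of Ccl5, Cxcl14, Cxcl16 (log2 fold change -2.10, SE 0.12) and Cxcl10, the last with an adjusted p of 0.172 without wild-type array 1 and 0.191 without array 2. Without wild-type array 2, 6 of the genes rose. Pf4 and Ppbp are counted both here and among erythroid and platelet markers, a list that moved with genotype (adjusted p = 0.00257; adjusted p = 0.429 with an estimated correlation). Of 14 inflammatory cytokines and mediators, 3 rose and 1 fell (4 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.320). Csf1, Il1a (log2 fold change 1.71, SE 0.31) and Il1rn, the antagonist of the IL-1 receptor (0.96, SE 0.11), rose, and the acute phase gene Saa3 fell (-2.12, SE 0.10); 2 genes fell without knockout array 2. Tnf, also named after its value was seen, was 450 ± 26.9 in wild-type and 519 ± 49.6 in the knockout (adjusted p = 0.297). Among 24 genes of the NF-kB pathway and its feedback loops, 5 rose and 7 fell over all genes and also adjusted over the list alone (adjusted p of the list = 0.320). Ier3 (log2 fold change 1.69, SE 0.11) and Malt1 (0.90, SE 0.11) rose, and Nfkbiz fell. The counts of this list were 2 and 2 without wild-type array 1, 3 and 2 without wild-type array 2, and 3 and 8 without knockout array 2.

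The list of interferon-stimulated genes lay below all other genes at the preset correlation (camera adjusted p = 9.96e-07, the smallest of all lists) but did not pass with an estimated correlation (adjusted p = 0.569). Of 32 tested members, 14 fell, none rose and 18 did not pass (17 fell and 1 rose adjusted over the list alone). The tetratricopeptide repeat gene Ifit2 fell from 681 ± 68.7 to 226 ± 60.2 (SD, n = 2 each; log2 fold change -1.55, SE 0.17, adjusted p = 0.000212). Irf7, the factor that drives interferon genes, had a log2 fold change of -1.28 (SE 0.14), the apoptosis factor gene Xaf1 of -1.09 (SE 0.12) and Oas3, which makes the activator of RNase L, of -1.11 (SE 0.13). The median log2 fold change of the list, -0.47 with all arrays, was -0.56 without wild-type array 1 and -0.39 without wild-type array 2. It was -0.40 without knockout array 1 and -0.57 without knockout array 2. Of 22 genes of the Toll-like receptor pathway, 6 fell and none rose (9 fell and 1 rose adjusted over the list alone), and the list lay below all other genes (adjusted p = 0.00170; adjusted p = 0.429 with an estimated correlation). Cd14, the co-receptor for lipopolysaccharide, fell from 5384 ± 268 to 1970 ± 255 (log2 fold change -1.45, SE 0.12). Irak3, a brake on the pathway, had a log2 fold change of -1.01 (SE 0.11) and the receptor gene Tlr2 of -0.68 (SE 0.15). Tlr2 did not pass without wild-type array 1 (adjusted p = 0.0767) or array 2 (adjusted p = 0.0977), and the number of genes of this list that fell was then 3 and 2. Without knockout array 1, 9 fell and 1 rose. Of 10 genes of MHC class II presentation, 2 rose and 2 fell (2 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.792). H2-DMa rose (log2 fold change 0.84, SE 0.13). H2-Aa (-0.62, SE 0.17, adjusted p = 0.0337) and H2-Ab1 (-0.64, SE 0.19, adjusted p = 0.0463) fell, but neither passed with quantile normalization or with median scaling. Without wild-type array 1, wild-type array 2 or knockout array 1 their adjusted p lay between 0.0569 and 0.354. The number of genes that fell was 0 without either wild-type array and 1 without knockout array 1, and 1 gene rose without wild-type array 2.

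The lists of cholesterol synthesis and of PPAR targets lay above all other genes at the preset correlation but did not pass with an estimated correlation (adjusted p = 0.489 for both). Their estimated correlations were 0.202 and 0.139, above the preset 0.01, so their p-values at the preset one may be too small. Of 21 cholesterol synthesis genes, 9 rose and none fell (13 rose adjusted over the list alone; camera adjusted p = 3.72e-05). Sqle, which encodes squalene epoxidase, rose from 668 ± 15.2 to 1357 ± 47.4 (SD, n = 2 each; adjusted p = 0.000144). Hmgcs1 and Mvd, which act early in the pathway, had log2 fold changes of 0.91 (SE 0.13) and 1.09 (SE 0.16). With either wild-type array left out, 4 genes of the list rose, and without knockout array 1, 1 fell. Of 28 PPAR target and fatty acid oxidation genes, 8 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 0.000155). The lipid carrier gene Fabp4 rose from 1660 ± 31.6 to 3158 ± 225 (log2 fold change 0.92, SE 0.10) and the dehydrogenase gene Acadl from 1123 ± 80.2 to 1907 ± 27.6 (0.76, SE 0.10). Pparg itself had a log2 fold change of 0.52 (SE 0.11, adjusted p = 0.0125), with an adjusted p of 0.117 without wild-type array 1 and 0.153 without array 2. The number that rose was 3 without wild-type array 1, 2 without wild-type array 2 and 14 without knockout array 1, and none fell without wild-type array 2 or without knockout array 2. Of 19 LXR target and efflux genes, 3 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.320). Scd2 rose from 150 ± 14.4 to 1004 ± 21.8 (log2 fold change 2.62, SE 0.12). Abca1, the main exporter of cholesterol, fell from 1794 ± 133 to 968 ± 7.78 (-0.88, SE 0.10) and the phospholipid transfer protein gene Pltp had -0.63 (SE 0.10; adjusted p = 0.0709 without wild-type array 1). Without wild-type array 1, 1 gene of this list rose and 1 fell, and without wild-type array 2, 1 rose and 2 fell. Of 27 genes of glycolysis and the hypoxia response, 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0849). The glucose transporter gene Slc2a1 rose (log2 fold change 0.80, SE 0.10) and Ndrg1 fell (-1.65, SE 0.11). This list passed without wild-type array 1 (adjusted p = 0.0442), and 1 of its genes rose without either wild-type array; 5 rose without knockout array 1, and 2 fell without knockout array 2.

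**Figure D3:**
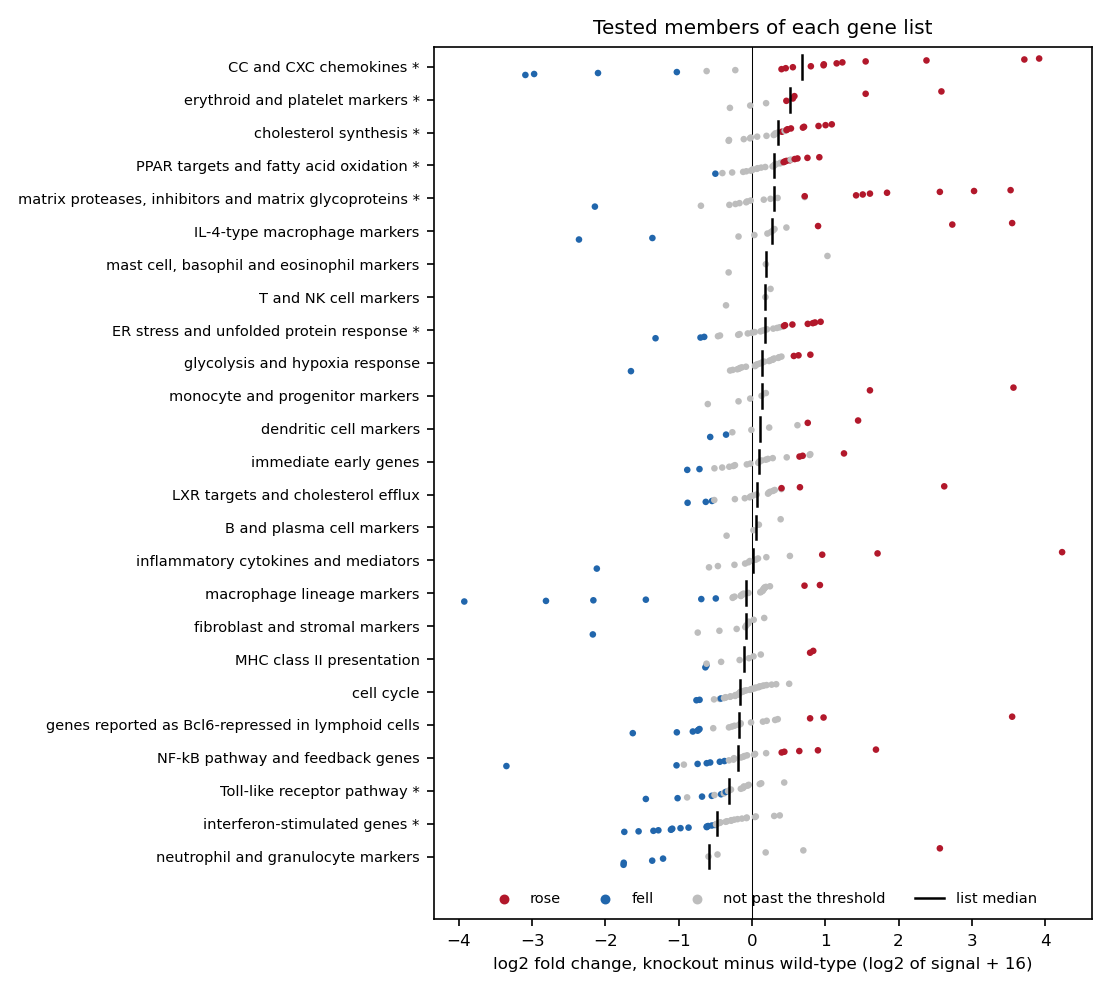
Log2 fold change (knockout minus wild-type, x axis) of each tested member of the gene lists (y axis), ordered by list median; red points rose, blue points fell and grey points did not pass the adjusted p threshold, black bars mark medians, and an asterisk marks lists with a camera adjusted p under 0.05 at an inter-gene correlation of 0.01. Among lists with an asterisk, the median of the interferon-stimulated genes is the lowest, at -0.47, and that of the chemokines the highest, at 0.68.

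Of 20 matrix proteases, inhibitors and matrix glycoproteins, 8 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.000259; adjusted p = 0.429 with an estimated correlation). Mmp13 rose from 358 ± 5.23 to 3058 ± 416, Mmp19 from 252 ± 17.4 to 3116 ± 681 and Mmp8 from 524 ± 14.1 to 3174 ± 131 (SD, n = 2 each), the last with a log2 fold change of 2.56 (SE 0.10). Plaur, the receptor of urokinase, had a log2 fold change of 1.51 (SE 0.10). Mmp14, named after its value was seen as the only gene of the list to fall, went from 286 ± 1.63 to 53.0 ± 13.8 (-2.14, SE 0.18). Without knockout array 1, 2 genes fell, and without knockout array 2, 3 fell. In the list of ER stress and the unfolded protein response, 7 of 25 genes rose and 3 fell (10 and 5 adjusted over the list alone; adjusted p = 0.0306; adjusted p = 0.494 with an estimated correlation). The members that rose with the smallest p were Manf (log2 fold change 0.83, SE 0.10), Pdia6 (0.94, SE 0.12) and Pdia4 (0.86, SE 0.13), a secreted ER protein and a pair of folding enzymes. The 3 that fell, Trib3, Asns and Ddit3, named after their values were seen, belong to the ATF4 and CHOP branch of the response. None of the 3 passed without wild-type array 2 (adjusted p = 0.0707, 0.124 and 0.107), nor did Ddit3 without wild-type array 1 (adjusted p = 0.0793). This list did not pass with quantile normalization (adjusted p = 0.0943), without wild-type array 2 (adjusted p = 0.109) or without knockout array 1 (adjusted p = 0.0701). The number that rose was 4 without wild-type array 1 and 3 without wild-type array 2; 5 fell without knockout array 2.

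Of 39 cell cycle genes, none rose and 3 fell (2 adjusted over the list alone; adjusted p = 0.173), and 0 fell without wild-type array 1, 1 without wild-type array 2, 5 without knockout array 1 and 7 without knockout array 2. Of this list 1 gene rose without wild-type array 2 and 1 without knockout array 1. Mki67, a marker of cycling cells named after its value was seen, was 604 ± 58.5 in wild-type and 525 ± 25.1 in the knockout (SD, n = 2 each; adjusted p = 0.287). The cyclin gene Ccnd3 fell (log2 fold change -0.72, SE 0.12), with an adjusted p of 0.0516 without wild-type array 1 and 0.0539 without array 2. Of 22 immediate early genes, 3 rose and 2 fell (4 and 5 adjusted over the list alone; adjusted p = 0.405). Myc rose from 248 ± 15.8 to 614 ± 55.7 (log2 fold change 1.26, SE 0.12) and Fos rose (0.65, SE 0.10), while the phosphatase gene Dusp1 fell (-0.72, SE 0.10). The number that fell in this list was 1 without wild-type array 1 and 5 without knockout array 1.

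Genes reported as repressed by Bcl6 in lymphoid cells were not higher as a group by the test. Of 21 tested, 3 rose and 6 fell (4 and 7 adjusted over the list alone), with an adjusted p of 0.366 for the list. Socs2 and Ccl3, the latter from 1735 ± 48.1 to 3433 ± 234 (SD, n = 2 each; log2 fold change 0.98, SE 0.10), rose. The cell cycle inhibitor gene Cdkn1b fell (-1.63, SE 0.22), as did Ptpn6 (-0.74, SE 0.11). The number that fell was 3 without wild-type array 1, and 2 rose and 4 fell without wild-type array 2. Of 12 markers of IL-4-type macrophages, 3 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.0601). Socs2, the growth factor gene Hbegf (log2 fold change 2.73, SE 0.19) and Egr2 (0.90, SE 0.10) rose, and the Fc receptor-like gene Fcrls fell (-2.36, SE 0.16). This list passed without wild-type array 1 (adjusted p = 0.0411).

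Most macrophage lineage markers did not pass the test, while the C1q genes and Cd14 fell. Of 28 macrophage lineage markers, 2 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.263); the list passed, downward, with quantile normalization (adjusted p = 0.00136) and without wild-type array 2 (adjusted p = 0.0304). C1qc, C1qa and C1qb (log2 fold change -2.16, SE 0.11) and Cd14 fell, while Csf1r, named after its value was seen, was 9624 ± 185 in wild-type and 10506 ± 1192 in the knockout (SD, n = 2 each; adjusted p = 0.529). Among the markers of other cell types, 9 neutrophil and granulocyte genes were tested, of which 1 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.160). Mmp8 rose, and Csf3r (-1.21, SE 0.11), S100a9 (-1.75, SE 0.19) and Lcn2 (-1.75, SE 0.22) fell. Of 8 erythroid and platelet markers, 5 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.00257; adjusted p = 0.429 with an estimated correlation). Car2, which encodes a carbonic anhydrase, rose from 24.6 ± 3.46 to 227 ± 17.7 (log2 fold change 2.59, SE 0.20). Pf4, a platelet chemokine that was bright in both genotypes, had a log2 fold change of 0.56 (SE 0.10), with an adjusted p of 0.0784 without wild-type array 1 and 0.117 without array 2. The number that rose was 2 without wild-type array 1, 1 without wild-type array 2 and 3 without knockout array 2. Of 7 monocyte and progenitor markers, Sox4 and Fn1 (1.61, SE 0.19) rose and none fell, also adjusted over the list alone (adjusted p = 0.0946); the list passed without wild-type array 1 (adjusted p = 0.0268) and without array 2 (adjusted p = 0.0358). Of 8 dendritic cell markers, 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.405), with Batf3 (1.45, SE 0.15) and Itgax (0.76, SE 0.10) higher; none fell without either wild-type array. Of 10 fibroblast and stromal markers, only Lox fell (-2.17, SE 0.40) and none rose, also adjusted over the list alone (adjusted p = 0.320). In 3 lists with fewer than 5 tested members no gene passed, whether over all genes or over the list alone. These were the T and NK cell markers (3 genes, median log2 fold change 0.18), the B and plasma cell markers (4 genes, 0.06) and the mast cell, basophil and eosinophil markers (3 genes, 0.19). Without knockout array 1, Cd22 of the B and plasma cell markers had a log2 fold change of 0.56. Siglecf of the mast cell, basophil and eosinophil markers had 1.34 in the same fit.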

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

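All tests in this part were chosen after the result they address was seen, except the comparison of the neighbours of Bcl6.

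Some control probe sets on the array also differed by genotype; of the controls, only those of actin and Gapdh and the bacterial ones are used above. The 3 probe sets of the control for the transferrin receptor, whose gene Tfrc lies near Bcl6, were higher in the knockout, 2.419-fold for the 3' probe set (200 to 507, adjusted p = 0.0015), 2.067-fold for the 5' one and 1.941-fold for the middle one. The control for the B1 repeat, a short mobile element, was 1.815-fold higher (1176 to 2150, adjusted p = 0.00145). In the other direction, the 5' control of 18S ribosomal RNA was lower in the knockout (202 to 44.6, log2 fold change -1.89, SE 0.27, adjusted p = 0.00282), while its 3' (-0.38, adjusted p = 0.494) and middle controls (-0.78, adjusted p = 0.107) did not pass. Of 2 controls named for the B2 repeat, 1 was lower (367 to 243, log2 fold change -0.56, adjusted p = 0.0216) and the brighter 1 did not pass (adjusted p = 0.443).

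Bcl6 signal remained in the knockout arrays, and its 2 probe sets differed in sign: 1 was lower by the threshold and the brighter 1 did not pass. Residual wild-type cells as the only source of the remaining signal are argued against by other genes. The lower probe set kept 34.0% of its wild-type signal. If wild-type cells kept their expression beside knockout cells, and signal followed their share, every gene should keep at least that much. Yet 42 called genes with a wild-type signal of at least 200 fell below it, against at most 1 between replicates. That premise was not tested, and large falls such as that of C1qa had been seen before the test was chosen. A wrong label on 1 array is argued against by the correlations, since the lowest within a genotype (0.983) exceeded the highest between genotypes (0.967) by 0.0161. What stays open is a probe set that lies outside the deleted part of the gene, which the labels do not settle, and a real change in transcription of the targeted allele; neither was tested.

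Of 32 interferon-stimulated genes 14 were lower in the knockout arrays by the threshold, and the list lay below all other genes at the preset correlation but did not pass with an estimated correlation (adjusted p = 0.569). A difference between the arrays' signal distributions that quantile normalization removes is argued against as the whole source: after it, the list median still lay below the median of all genes (difference -0.371, spread 0.0649, against -0.435 without it). The spread is the scaled median absolute deviation of the members over the square root of their number. It treats the members as independent, though their estimated correlation was 0.575, and so is too small. The point rests on how little the difference changed. Interferon tone that varies between samples whatever the genotype may be the source and cannot be told apart from genotype with 2 arrays each. The array medians of the list were 0.16 and 0.29 in wild-type and -0.36 and -0.12 in the knockout, so that the largest gap between replicates was 0.509 of the gap between genotypes, in a design whose smallest exact two-sided p is 0.333. An effect of Bcl6 loss on interferon signalling is another possible explanation, and it was not tested further.

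Alleles of the strain in which the knockout was made could change genes linked to Bcl6. Among the 100 tested genes nearest to Bcl6, 50 on each side, 11 changed (11%), with 6 higher and 5 lower, against 15.7% of the other 10678 genes (odds ratio 0.663, 95% interval 0.319 to 1.25, two-sided Fisher's exact p = 0.216). The share was not above that of other genes, but the interval still allows a small excess, and the test cannot show an excess confined to the closest genes. Linked alleles thus cannot be told apart from the effect of Bcl6 for these 11 genes, which include Tfrc and Dnajb11, a member of the ER stress list. Among them are also Rtp4 (log2 fold change -1.01), Lpp (1.10) and Ccdc50 (-0.59), which with Dnajb11 lie at most 5 tested genes from Bcl6. As close but not past the threshold were Lppos, Il1rap, Mb21d2, St6gal1, Rfc4 and Eif4a2. These close genes were named after their values were seen.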

How the results depend on the processing

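The alternatives were all chosen before the data were examined. The number of changed genes (1691; 791 higher, 900 lower) was 881 (440 and 441) with no filter, which tests more genes, and 681 (329 and 352) with eBayes without a trend; median scaling gave 570 lower genes, and the cause of the changes under trend and scaling was not tested. With 1 array left out, 579 to 2799 genes changed, 303 to 1284 higher and 273 to 1515 lower. The labels do not say that replicate numbers mark a shared batch or day, and the correlation of same-numbered arrays' deviations (r = 0.13 over 2 pairs) does not settle it, so arrays were not paired; with the replicate block 2490 genes changed (1115 higher, 1375 lower), the monocyte and progenitor list passed (adjusted p = 0.0483), and so did Bcl6 probe set 1421818_at (log2 fold change 0.39, adjusted p = 0.0225); median scaling gave that probe set 0.48. Other settings kept the total within 1.5 times, from 1251 (mean of all probe sets of a gene) to 2363 (adjusted p under 0.1). The genes changed at least 2-fold, 166 higher and 178 lower, were 106 and 96 with a pseudocount of 64. Higher genes were also the more numerous of these with quantile normalization (185 and 146) and median scaling (198 and 130).

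With an estimated correlation no list passed: adjusted p = 0.4288 for chemokines, the Toll-like receptor pathway, matrix proteases and erythroid and platelet markers, 0.4891 for cholesterol synthesis and PPAR targets, 0.4938 for ER stress and 0.5694 for interferon-stimulated genes. That test has 2 residual degrees of freedom, too few for a list to pass easily. Chemokines, matrix proteases and erythroid and platelet markers did not pass although their estimated correlations were negative (-0.0075, -0.017 and -0.098). The estimates were 0.575 for interferon-stimulated genes, 0.202 for cholesterol synthesis and 0.139 for PPAR targets, far above the preset 0.01. For ER stress and the Toll-like receptor pathway they were 0.053 and 0.016. If members vary together that much, the p-values of these lists at the preset correlation are too small. No conclusion is drawn from the outcome of the test with an estimated correlation. ER stress was also lost with quantile normalization (0.0943), the mean of all probe sets (0.0595) and no trend (0.0555), and ranged from 0.0107 to 0.109 with 1 array left out. Lists gained a call with quantile normalization (macrophage lineage, downward, 0.00136), with the mean of probe sets (IL-4-type markers 0.0258, glycolysis 0.0250), with all probe sets (inflammatory cytokines 0.000196, glycolysis 0.0213, macrophage lineage 0.0174, monocyte and progenitor 0.000839) and without a trend (IL-4-type markers 0.0458). With 1 array left out the adjusted p ranged from 0.0411 to 0.132 for IL-4-type markers, 0.0442 to 0.311 for glycolysis, 0.0268 to 0.134 for monocyte and progenitor markers and 0.0304 to 0.492 for macrophage lineage markers. The other 7 lists called at the preset correlation kept their direction and call in every setting that tested them but the estimated correlation; at the 75th percentile filter only 2 erythroid and platelet markers were left, too few for a test.

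Of 109 named genes, 92 were called. Calls were lost for 17 without wild-type array 1, 20 without wild-type array 2, 2 without knockout array 1 and 1 without knockout array 2; no trend lost 17, no filter 11, the mean of probe sets 10, and every other setting at most 4. The sign of Bcl6 turned with the mean of its probe sets (log2 fold change -0.47), since the probe sets differ in sign. Fits without a wild-type array take their residual spread from the knockout pair alone, and those without a knockout array from the wild-type pair. The SD of the difference between replicates was 0.341 for the knockout pair and 0.256 for the wild-type pair. A call lost without a wild-type array thus need not rest on that array. The cause of the other changes was not tested. Signals near the bacterial controls limit what can be said of dim genes.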

Other observations

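Genes in this part were chosen after their values were seen, and no hypothesis is attached to them. Each call holds with any 1 array left out unless said otherwise. Of 10 genes of the complement system and its receptors, 5 fell, 2 rose and 3 did not pass. The 3 chains of C1q fell together with factor B (Cfb, log2 fold change -2.44, SE 0.32) and the receptor gene C5ar1 (-0.94, SE 0.10), whereas the integrin chains that bind complement fragments, Itgam (0.93, SE 0.10) and Itgax (0.76, SE 0.10), rose. C3ar1 (5320 and 4656), Cfp and C1ra did not pass; Cfp passed, upward, without knockout array 1 (adjusted p = 0.0131). Among genes of blood clotting, tissue factor (F3) rose, from wild-type signals near or below the bacterial controls to 238 ± 63.1. Factor VII (F7) rose from 63.3 ± 5.30 to 225 ± 24.7 and factor X (F10) from 198 ± 15.6 to 634 ± 10.8 (log2 fold change 1.60, SE 0.12, adjusted p = 1.73e-05), and the urokinase gene Plau (1.84, SE 0.41, adjusted p = 0.0149) and its receptor gene Plaur rose. The Plau signals were 378.1 and 110.5 on the knockout arrays and 54.3 and 39.1 on the wild-type arrays, so the size of its rise is uncertain. The protein C receptor gene Procr rose too (0.46, SE 0.10, adjusted p = 0.0120), a call lost without wild-type array 1 (adjusted p = 0.186) or array 2 (0.135), and the factor XIII gene F13a1 did not pass (adjusted p = 0.499). The inhibitor gene Tfpi fell (-0.53, SE 0.16, adjusted p = 0.0468), a call lost without wild-type array 1 (adjusted p = 0.288), wild-type array 2 (0.260) or knockout array 1 (0.0671). The anticoagulant gene Thbd had -0.45 (SE 0.15, adjusted p = 0.0741), and passed without knockout array 1 (adjusted p = 0.0275).

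The growth factor gene Kitl rose from 189 ± 4.88 to 689 ± 9.76 (log2 fold change 1.78, SE 0.11, adjusted p = 7.01e-06), Il1rl2, a receptor of the IL-36 family, from 57.5 ± 7.28 to 389 ± 102 (2.44, SE 0.19) and the IL-1 receptor gene Il1r1 from 87.5 ± 42.9 to 408 ± 18.6 (2.10, SE 0.24). The transferrin receptor gene Tfrc rose at its own probe set too, from 995 ± 34.3 to 2002 ± 329 (0.99, SE 0.12, adjusted p = 0.000566), as on the control probe sets. Tfrc is 1 of the 11 changed genes among the 100 tested genes nearest to Bcl6, so for it linked alleles cannot be told apart from the effect of Bcl6 (Fisher's exact p = 0.216 for these neighbours). The iron exporter gene Slc40a1 (0.46, SE 0.10) and the haem oxygenase gene Hmox1 (0.40, SE 0.10) rose, calls that were lost without wild-type array 1 (adjusted p = 0.189 and 0.207) and without array 2 (0.138 and 0.258). The ferritin gene Fth1 was 13282 ± 777 and 14609 ± 1890 (adjusted p = 0.523). Among surface proteins, Pdpn (2.12, SE 0.12) and Cd164 (1.88, SE 0.10) rose, and Slamf9 (-2.60, SE 0.14), Tmem176b (-2.61, SE 0.14), Tmem176a (-2.41, SE 0.20) and the integrin gene Itgal (-2.08, SE 0.17) fell. Of 2846 probe sets above the filter that were not named, because the annotation does not list them or gives several symbols, 80 were higher and 90 lower in the knockout.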
